A study of Homo sapiens with 18 samples.

How the data were processed

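The data were 1 table of 54613 probe sets by 18 arrays, 1 array for each of 18 cell lines labelled CRC. Biotin-labelled total RNA was measured on a human whole-transcriptome array. The deposited values are log2 intensities that the authors made with RMA in the affy package, per the submitters' processing notes; the versions are not given in the sources used here. They ran from 2.31 to 13.71, with array medians between 3.65 and 3.69, and were used without further normalization. Per the labels, 10 lines were grown in DMEM/F-12 and 8 in RPMI-1640, and this was the 1 grouping the labels gave; no subtype was given and none was assigned. Each line was measured once, so no replicate check was possible, and the number of arrays limits the precision.

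Of the probe sets, 40914 matched 1 gene, 864 several and 12835 none, and those with 1 gene were used, giving 19739 genes. Gene names came from the array annotation, and 40858 of the single-gene probe sets had an Entrez ID in a RefSeq gene table of assembly GRCh38.p14, which was used for names and gene order alone. Each gene was read from the probe set with the highest mean. The background level was the 95th percentile of 66 probe sets of 44 measured genes (of 50 listed), 5.06 log2 units. The genes were picked as restricted to tissues other than the colon, and this choice was not checked gene by gene. That set included KERA and RLBP1, which reached 10.57 in HUTU80 and 8.28 in RCM1, so its upper percentiles may hold signal. A gene was kept if it exceeded this level in at least 1 line (12766 genes; 6565 did so in all lines). Signal over background limits what can be said of dim genes: at or under 5.06 a value is read as not detected. For each gene with several probe sets the 2 with the highest mean were compared by correlation and by the SD between their deviations.

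The groups, gene lists, gene pairs, and the tests, thresholds and alternatives of the report's comparisons were fixed before the data were examined. Genes with a range of 3 log2 units (8-fold) or more were called variable, and similarity of lines was their Pearson correlation over these genes, with principal components of the centred values. Gene lists (24, with 425 members, of which 399 were measured) came from general knowledge of the field. The 22 lists with at least 3 members above background were tested. Coherence of a list was the mean pairwise correlation of its members against 10000 random lists matched in 20 expression bins. The position of a line was the median deviation of the members from their panel mean, called high or low in the upper or lower 2.5% of random lists. Leukocyte and endothelial lists had fewer than 3 members above background and are given as values. A gene was called restricted to a line if it lay at least 3 log2 units above, or below, every other line; for high genes that line, and for low genes all other lines, had to exceed the background level.

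Gene pairs were tested by Pearson and Spearman correlation with 100000 permutations, enumerated exactly under 10 lines. The smallest p the permutations can give was 1e-05 for pairs and 1e-04 for lists. Where either gene fell into clusters (a gap over 0.333 of its range with at least 3 lines on each side) the pair was tested within clusters of at least 6 lines. Each correlation was repeated without the 2 lines farthest from the median and within each medium. The media were compared with limma (trend), and lists with camera, at a preset and at an estimated correlation, and fry. Benjamini-Hochberg adjusted p under 0.05 was called, over all genes and, where stated, adjusted over the list alone. In tests chosen after the data were seen, runs of neighbouring genes were sought in windows of 5 genes along GRCh38.p14 with 1000 shuffles of gene order.

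The genes named were set by rule: the 20 with the largest SD, 4 per list by SD with all mismatch repair genes, 2 high and 1 low restricted gene per line by gap, the genes of the pairs, 5 loadings on each side of component 1, and 3 genes per direction for the media where none passed; this gave 171 genes. Other genes named in the closing section were chosen after their values were seen. Alternatives were the mean of all probe sets, the probe set with the largest SD, array scaling, other background levels, other ranges and gaps, random lists matched on mean and SD in 5 SD bins, Spearman correlation, other limma settings, and leaving out each line. The scripts were tested on simulated data. Shifts of 1, 2, 3 and 4 log2 units between the media were called in 40, 78, 88 and 94 percent of 50 genes each, with 6 of 12566 unshifted genes called. These genes were drawn independently, unlike real genes, and all shifts were planted at once. The percentages may therefore not carry over to the real comparison of media. All 20 planted lists and none of 20 unrelated lists were called, 23 of 342 unrelated positions were called, 98 of 100 planted pairs and 3 of 100 unrelated pairs passed at unadjusted p, and the planted run was found, with 2 of 17 other lines called. Software was python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9, R 4.3.3 and limma 3.58.1.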

Results

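Gene expression was measured in 18 cell lines labelled as colorectal cancer (CRC), each on 1 whole-transcriptome microarray hybridised with biotin-labelled total RNA. The origin of each line was not checked. The lines were HCT116, KM12, RKO, SW48, RCM1, SNUC1, HT55, SW948, SW1463, LS513, LS180, CL40, MDST8, COLO320HSR, NCIH716, CAR1, HUTU80 and OUMS23, established cancer cell cultures that are propagated in the laboratory. Per the labels, 10 lines (RKO, SW48, HT55, SW948, SW1463, LS180, CL40, CAR1, HUTU80 and OUMS23) were grown in DMEM/F-12 medium and 8 (HCT116, KM12, RCM1, SNUC1, LS513, MDST8, COLO320HSR and NCIH716) in RPMI-1640. The series concerns the molecular subtypes of CRC in laboratory models; the labels used here give no subtype for any line and none was assigned. Each line was measured once, so differences between single lines are given as values without a replicate error, and the number of arrays limits the precision. Array medians lay between 3.65 and 3.69 on the log2 scale, and 9015 to 9580 of the 19739 measured genes exceeded the background level of 5.06 in a given line. Values under that level are read as not detected, and the order of lines under it carries no meaning. For 6265 genes read by several probe sets, the median correlation of the brightest pair over the lines was r = 0.91, and the median SD between them was 0.24 log2 units.

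The first comparison asked which genes differed most between the lines. AGR2, a protein of the secretory pathway of mucus-producing cells, had the largest spread (SD 4.50 log2 units, n = 18) and ran from 2.81 in HCT116 to 13.12 in NCIH716. GPX2, a glutathione peroxidase of the gut epithelium, ran from 2.89 in COLO320HSR to 12.53 in SNUC1 (SD 4.25), and the tetraspanin TSPAN8 from 3.22 in RKO to 13.09 in CL40 (SD 4.20). LGALS4, a lectin of enterocytes, reached 12.52 in SW948 and 3.20 in CAR1, and FABP1, a fatty acid carrier of enterocytes, reached 13.02 in SNUC1 and 2.93 in COLO320HSR. KRT20, an intestinal keratin, reached 12.34 in SNUC1 and 3.12 in MDST8, and VIL1, which bundles actin in microvilli, reached 11.72 in HT55 and 3.07 in HCT116. CDH17, an intestinal cadherin, ran from 3.27 in MDST8 to 11.62 in SNUC1, and CEACAM5, the carcinoembryonic antigen, from 3.24 in CAR1 to 12.26 in SNUC1. TFF3 and SPINK4, products of goblet cells, were highest in LS513 at 12.54 and 12.20, and TFF3 was at background in 8 lines. KRT19, a keratin of simple epithelia, reached 12.74 in CL40 and 3.39 in RKO.

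VIM, the intermediate filament of mesenchymal cells, ran the other way, from 3.04 in SW948 to 13.19 in MDST8 (SD 3.93), although its 2 probe sets differed by an SD of 2.20. TGFBI, an extracellular matrix protein, reached 12.91 in MDST8 and 3.28 in HCT116, and DKK1, a secreted WNT antagonist, reached 12.79 in HUTU80 and 3.27 in HT55. The S100 calcium-binding proteins were spread as widely. S100A14 ran from 3.12 in RKO to 11.92 in SNUC1, S100P from 3.67 in COLO320HSR to 12.61 in CL40, and S100A6 from 2.88 in COLO320HSR to 13.25 in KM12. AKR1C3, an aldo-keto reductase, ran from 3.01 in RKO to 12.77 in NCIH716, and MAGEA6, a cancer-testis antigen, from 3.20 in SW948 to 12.05 in NCIH716. Both belong to families of similar sequence, so related transcripts are not ruled out as a source of their signals. Over all genes, 4892 of the 12766 above background in at least 1 line (38.3%) differed by 3 log2 units or more between the highest and the lowest line. Of these, 700 were above background in every line. The median SD over the lines was 0.64 log2 units. A range of 2 or 4 log2 units in place of 3 gave 8105 or 3254 genes.

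Whole profiles were compared by principal components and by correlation. On principal component 1 of the variable genes, which held 27.7% of their variance, the most negative loadings were those of GPX2, LGALS4, TSPAN8, VIL1 and AGR2. The most positive were those of VIM, of FERMT2, an integrin adaptor, of TUBA1A, a tubulin, of GPX8, an endoplasmic reticulum peroxidase, and of CALD1, an actin-binding protein. FERMT2 was highest in HUTU80 (11.18) and at background in KM12 (2.76), and CALD1 was highest in OUMS23 (10.82) and at background in HT55 (2.73). TUBA1A ran from 3.32 in LS180 to 11.86 in MDST8, and GPX8 from 2.78 in HT55 to 9.98 in RKO. CL40 (−69.2), LS513 (−67.6), SNUC1 (−63.3) and HT55 (−62.9) had the lowest scores on this component, and HUTU80 (89.7), MDST8 (86.6) and COLO320HSR (75.9) the highest. Component 2 placed NCIH716 at 92.5 and CAR1 at −64.3. The correlation between 2 lines over the variable genes had a median of r = 0.54 over 153 pairs of lines. It was highest for SW948 and SW1463 (r = 0.86) and lowest at r = 0.30. These are correlations across genes within pairs of samples, and genes are not independent replicates.

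**Figure D1:**
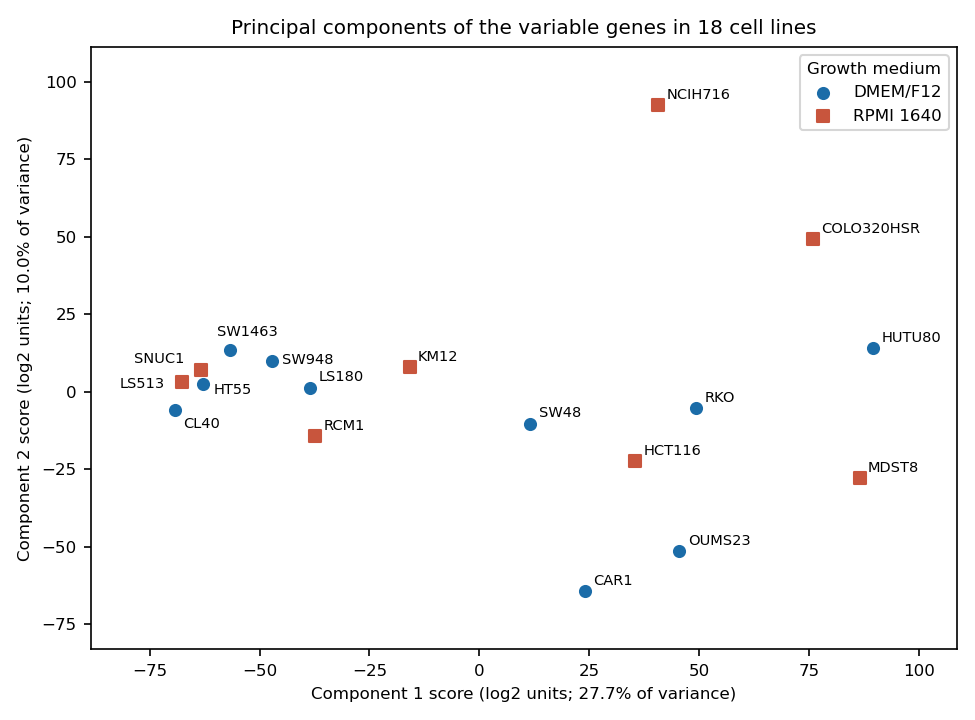
Scores of the 18 cell lines on principal components 1 (x axis, 27.7% of variance) and 2 (y axis) of the centred log2 values of the variable genes, with circles for lines grown in DMEM/F-12 and squares for RPMI-1640. CL40 lies at −69.2 and HUTU80 at 89.7 on component 1, and both media occur on either side of 0.

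The second comparison asked which gene programmes varied together over the panel and where each line stood. For some lists only a part of the lines called high or low is named. Over all lines pooled, epithelial junction and adhesion genes moved almost as a block (mean pairwise r = 0.81 over 23 members). Their median deviation from the panel mean was 0.71 to 2.13 log2 units in 13 lines, highest in CL40, and far below it in NCIH716 (−2.65), RKO (−3.98), HUTU80 (−4.12), COLO320HSR (−4.35) and MDST8 (−4.55). CDH1, which encodes E-cadherin, was 11.58 in CL40 and 3.16 in MDST8. EPCAM, an epithelial adhesion molecule, was 12.50 in LS513 and 3.74 in COLO320HSR. CLDN3, a tight junction protein, was 10.62 in LS513 and 2.58 in COLO320HSR. The mean r of this list pooled all lines, although CDH1 and EPCAM fell into clusters. Within the 13 lines, CDH1 with EPCAM had r = 0.67 (permutation p = 0.0120, adjusted p = 0.0698), and r = 0.27 without HCT116 and CAR1. The list was not tested within clusters, so its mean r may largely restate the split of the lines. The mesenchymal list was high in MDST8, with a median deviation of 4.05 and 20 of its 24 members 1 log2 unit or more above the panel mean. CAR1, high for the epithelial list, was also called high (0.39, 11 of 24 members). It lay at percentile 97.9 of the random lists, close to the limit of the upper 2.5%, and MDST8 at percentile 100. With random lists matched on SD, 1 of these 2 calls stayed. FN1, fibronectin of the extracellular matrix, was 12.82 in MDST8 and 12.70 in HUTU80. RKO (−0.54), COLO320HSR (−0.74), NCIH716 (−0.30) and HUTU80 (0.01), which were low for the epithelial list, did not stand high for the mesenchymal list as a whole. COLO320HSR was called low, 1 of 12 lines called low for this list, and 3 of these low calls stayed with random lists matched on SD. Members were split in HUTU80, with 9 above and 5 below the panel mean by 1 log2 unit or more, and in NCIH716, with 8 and 6.

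Intestinal enterocyte identity genes were high in HT55 (median deviation 4.20 log2 units, 19 members), CL40 (3.40), SNUC1 (2.88), SW1463 (2.55), SW948 (1.57) and also LS513. Their lowest medians were those of CAR1 (−2.12), MDST8 (−2.10) and OUMS23 (−2.08). Goblet and secretory genes were called high in 7 lines, among them NCIH716 (2.31), LS180 (2.24), LS513 (2.04) and CL40 (1.42). They were lowest in CAR1 (−1.32). AGR3, a relative of AGR2, was 10.73 in SW1463, 10.50 in NCIH716 and 2.81 in CAR1. The neuroendocrine list stood far above the panel in NCIH716 alone (5.55), where all 13 members were 1 log2 unit or more above the mean. CPE, which processes prohormones, was 11.35 there and 2.97 in KM12, and SCG2, a granin of secretory granules, was 10.66 there and 3.26 in SNUC1. DDC, which decarboxylates aromatic amino acids, was as high in SW948 (11.25) as in NCIH716 (11.20), and UCHL1, a neuronal ubiquitin hydrolase, was highest in COLO320HSR (12.17).

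Hepatocyte genes were high in NCIH716 (median deviation 3.32) and SW1463 (0.20). In NCIH716 ALB, which encodes serum albumin, was 11.80, TTR 7.12 and APOH 6.86; SERPINA1, a protease inhibitor, was highest in CAR1 (12.32). That list had 5 members above background in at least 1 line. With the mean of all probe sets its position in NCIH716 was no longer in the upper tail, while that in SW1463 was. In SW1463, however, ALB was at most 3.17 and TTR was 3.71, both under background. Its small median thus draws on values read as not detected, and little can be read from that call. Squamous genes were high in CAR1 (1.51), where KRT14, a basal keratin, was 10.06 and DSC3, a desmosomal cadherin, 8.18; S100A2 was highest in RKO and SPRR1B in LS513 (9.75). Gastric genes were high in LS180 (1.19) and KM12 (0.50). CTSE, an aspartic protease of the stomach, was 11.04 in CL40, the trefoil peptide TFF2 was 9.93 in CL40, SOX2 was 11.06 in HUTU80, and ANXA10 was 10.85 in NCIH716. Of 11 measured leukocyte genes, 1 exceeded background in any line: PTPRC, the pan-leukocyte surface protein, at 6.68 in SW48 and 6.40 in COLO320HSR. Of 8 endothelial genes, CDH5 did so, at 5.87 in OUMS23.

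Signalling targets separated other lines. WNT targets and crypt base genes, which mark stem cells of the intestinal crypt, were high in HT55 (median deviation 2.40), LS513 (1.18) and LS180 (0.89) and low in RKO (−1.75), NCIH716 (−1.54), HCT116 (−1.50) and CAR1 (−1.19). AXIN2, a negative feedback gene of the WNT pathway, was 11.44 in HT55 and SW48 and 3.92 in NCIH716. ASCL2, a transcription factor of crypt stem cells, was 10.37 in SW1463 and 3.27 in HCT116, and APCDD1, a membrane WNT inhibitor, was 11.95 in COLO320HSR and 3.95 in HCT116. OLFM4, a crypt base glycoprotein, was above background in SW948 (11.31) and SW1463 (10.63) and in no other line. Targets of YAP and TEAD were high in CAR1 (2.76), MDST8 (1.36) and HUTU80 (1.02) and low in NCIH716 (−1.28). CCN1 and CCN2, matricellular proteins, were 11.94 and 11.81 in CAR1, and NT5E, an ecto-nucleotidase, was highest in MDST8 (10.16). TGF-beta response genes were high in SW48 (1.01), HUTU80 (1.00) and MDST8 (0.99) and low in OUMS23 (−1.55). PMEPA1, a feedback inhibitor of that pathway, was 11.54 in CAR1 and 2.88 in OUMS23, TGFB2 was 9.96 in HUTU80, and BAMBI, a pseudoreceptor, was 12.66 in SW48. EGFR and MAPK genes were called high in 10 lines, among them RCM1 (1.41), and low in 4, among them COLO320HSR (−2.76) and OUMS23 (−2.32). With random lists matched on SD, 3 high and 2 low calls stayed. EREG, a ligand of EGFR, was 10.33 in HCT116 and 2.46 in OUMS23, TGFA, another ligand, was 10.08 in CAR1, ERBB3, a partner receptor, was 11.13 in HT55, and DUSP4, a MAPK phosphatase, was 11.22 in SW48.

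Interferon response genes were called high in 5 lines. In CL40 (median deviation 3.12) all 22 members lay 1 log2 unit or more above the panel mean. In RCM1 (1.78) 16 of 22 did. IFI27 was 11.83 in CL40 and 11.36 in RCM1, OAS1, a sensor of double-stranded RNA, was 11.12 in CL40, and IFIT3 was 9.57 there. IFI6 was highest in OUMS23 (11.52), whose list median was −0.73. MHC class I presentation genes were called high in 7 lines, among them LS513 (1.93), CL40, SW1463 (1.37), CAR1 (1.08) and RCM1 (0.92). They were called low in 7, among them HUTU80 (−1.17), OUMS23 (−0.99), KM12 (−0.76) and SNUC1 (−0.69). HLA-B, a class I heavy chain, was 12.41 in LS513 and 5.70 in COLO320HSR, HLA-C was 12.45 and 5.55 in these lines, and PSMB8, an immunoproteasome subunit, was 10.36 in LS513 and 2.72 in HUTU80. Targets of p53 were high in MDST8 (1.66) and LS513 (0.78). FAS, a death receptor, was 8.74 in MDST8, GDF15, a stress cytokine, was 12.20 in LS513 and 2.94 in COLO320HSR, PHLDA3 was 8.94 in CAR1, and TP53INP1 was 9.14 in OUMS23.

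Cell cycle genes, which carry out DNA replication and mitosis, were high in HCT116 (0.51), HUTU80 (0.50) and SW48 (0.43) and low in SNUC1 (−0.49), CL40 (−0.33) and LS513 (−0.29, not with the mean of all probe sets). MCM2, a subunit of the replicative helicase, was 7.91 in MDST8 and 11.09 in OUMS23. MKI67, a marker of dividing cells, ran from 7.93 in LS180 to 10.57 in RCM1, MCM5 from 7.39 in HT55 to 9.84 in HCT116, and the mitotic kinase AURKB from 7.44 in CL40 to 9.73 in KM12. MYC targets and ribosome biogenesis genes were high in HCT116 (0.42) and RKO (0.37) and low in CAR1 (−0.41), CL40 (−0.35), LS513 (−0.25) and HT55 (−0.23). With the mean of all probe sets RKO, CAR1, LS513 and HT55 left the tails, and HT55 also did with array scaling and with random lists matched on SD. MYC itself ran from 9.42 in MDST8 to 13.09 in COLO320HSR. WDR43 and BOP1, which act in ribosome assembly, had SDs of 0.64 and 0.58, and MYBBP1A had 0.61. Mismatch repair genes were low in CL40 (−0.75). PMS2, EXO1 and MSH6 were 5.73, 6.11 and 8.99 in CL40 against panel means of 7.18, 7.57 and 9.63; this position left the lower tail with the mean of all probe sets. MSH3, PMS1 and MLH3 had SDs of 0.33, 0.54 and 0.72, and EPM2AIP1, placed on this list, ran from 2.76 in RKO to 9.05 in RCM1.

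Cholesterol and fatty acid synthesis genes were low in RKO (median deviation −0.93), where HMGCS1, an early enzyme of the pathway, was 7.28 and INSIG1, a sterol sensor, 8.83. They were highest in COLO320HSR (0.63), where HMGCS1 was 10.12. SQLE, which epoxidises squalene, was 12.98 in NCIH716, and SC5D was 10.67 in SNUC1. Fatty acid oxidation and ketogenesis genes were low in MDST8 (−1.47), where ACSL5, an acyl-CoA synthetase, was 2.87, and high in LS513 (0.75) and, except with the mean of all probe sets, SW948 (0.69). CPT1A, the carrier enzyme of mitochondrial fatty acid import, was 10.13 in SW948 and 4.39 in COLO320HSR, PPARG was 9.99 in KM12 and PDK4 7.90 in COLO320HSR. Glycolysis and hypoxia genes were high in SW1463 (0.50), where NDRG1 was 10.58. SLC2A1, a glucose transporter, was 11.12 in RCM1 and 5.59 in MDST8, EGLN3 was 9.44 in OUMS23, and BNIP3, a mitophagy receptor, was above background in 6 lines, highest in COLO320HSR (11.43). Xenobiotic and glutathione genes were high in CL40 (0.87), LS180 (0.84) and SW948 (0.77) and low in HUTU80 (−1.42); CL40 and HUTU80 left the tails with random lists matched on SD. AKR1B10 was 10.93 and AKR1C1 11.72 in SNUC1, and ABCB1, a drug efflux pump, was 9.61 in SW948 and 2.79 in RKO.

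Of 22 lists tested, 19 had a mean pairwise correlation above that of random lists matched on expression, at Benjamini-Hochberg adjusted p under 0.05. For 14 of them the one-sided permutation p was 1e-04, the smallest that 10000 random lists can give. Unlike the gene pairs, the lists were pooled over all lines even where members fell into clusters. A high mean r can therefore rest on a split of the lines, and no list was tested within clusters. After the epithelial list, the highest mean r were those of MHC class I presentation (0.51), interferon response (0.50), neuroendocrine (0.47) and enterocyte genes (0.44), and the weakest call was mismatch repair (r = 0.15, adjusted p = 0.0441). Gastric (r = 0.09, adjusted p = 0.110), squamous (r = 0.09, adjusted p = 0.110) and hepatocyte genes (r = 0.24, adjusted p = 0.0506) did not pass. The neuroendocrine correlation rested on NCIH716 (r = −0.03, adjusted p = 0.687 without it). The mismatch repair call ended when any of RCM1, HT55, CL40, NCIH716, HUTU80 or OUMS23 was left out (adjusted p up to 0.121, r = 0.087, without CL40). Without RCM1, HUTU80 or OUMS23 r was still 0.14 (adjusted p = 0.0514, 0.0562 and 0.0601), so mainly the p moved. The call also ended, with a lower r, with the mean of all probe sets (r = 0.096, adjusted p = 0.110) and the probe set with the largest SD (r = 0.10, 0.106). With array scaling (r = 0.14, 0.0614), the higher background level (r = 0.15, 0.127) and Spearman correlation (0.13, 0.0577) it ended with a correlation close to the 0.15 above, so mainly the p moved. The gastric list passed without NCIH716 (r = 0.18, adjusted p = 0.0374). The hepatocyte list passed without any of KM12, SNUC1, SW948, SW1463, LS513, LS180, CL40 or OUMS23 (adjusted p down to 0.0185, r = 0.41, without OUMS23). Apart from OUMS23, leaving out these lines gave r of 0.24 to 0.25, close to the 0.24 above, so mainly the p moved. The hepatocyte list also passed with the probe set of the largest SD (r = 0.24, 0.0476) or no background level (r = 0.080, 0.0267). Of 396 combinations of list and line, 98 lay in the upper and 118 in the lower 2.5% of random lists. For lists of unrelated genes 19.8 would be expected. Members of a coherent list move together, so their medians reach the tails more often, and the excess is no evidence beyond coherence. When random lists were also matched on SD, 132 of these 216 stayed in their tail.

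**Figure D2:**
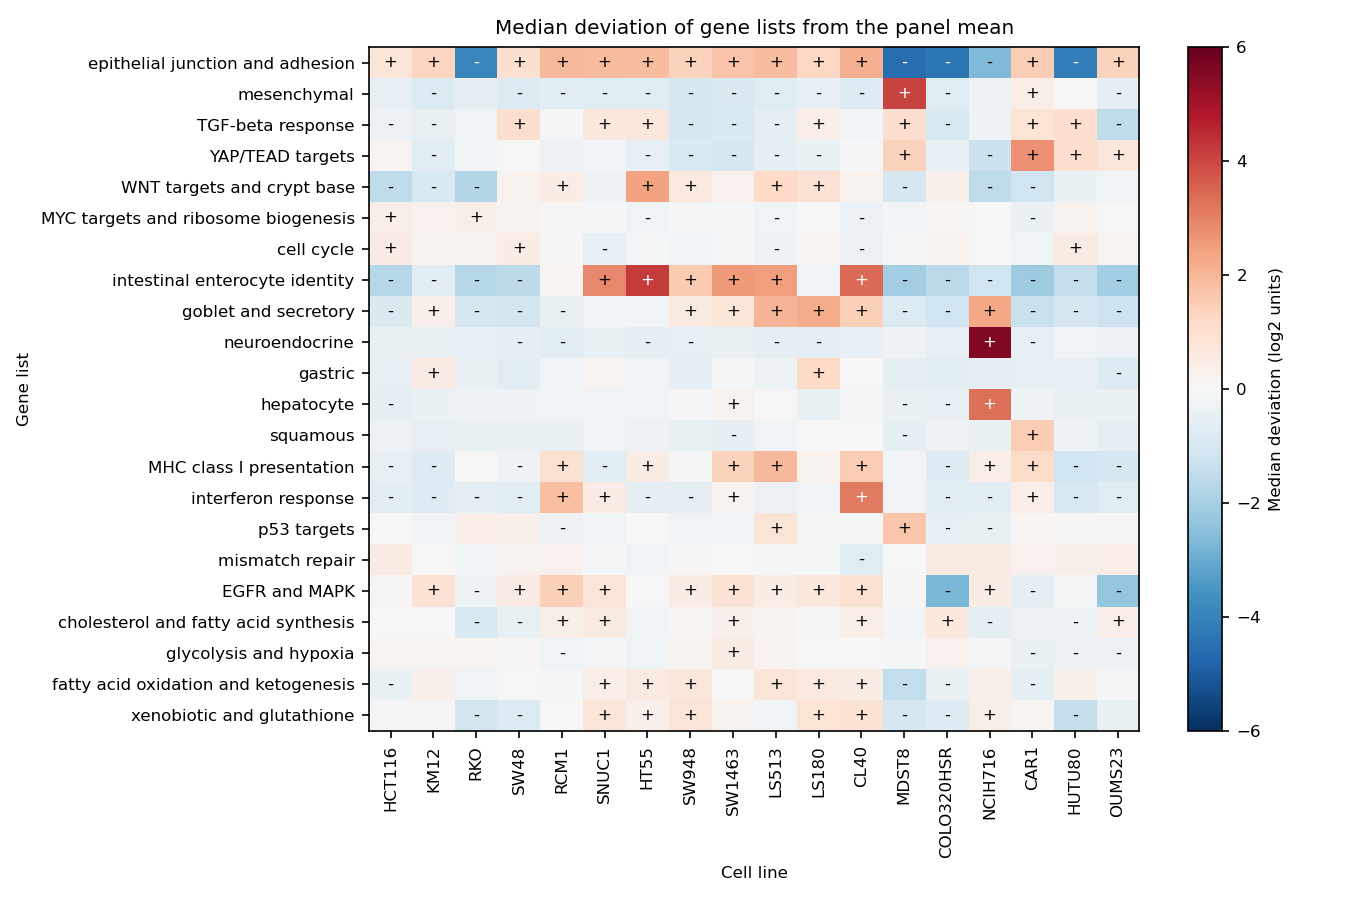
Median deviation from the panel mean (colour, log2 units) of the members of 22 gene lists (y axis) in 18 cell lines (x axis); plus and minus signs mark medians in the upper and lower 2.5% of 10000 expression-matched random lists. The epithelial list falls to −4.55 in MDST8, the neuroendocrine list reaches 5.55 in NCIH716 and the interferon list 3.12 in CL40.

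The third comparison asked which genes set a single line apart from all others. NCIH716 had the most genes at least 3 log2 units above the next line, 92 of 419. Its widest gaps were those of COL14A1, a fibril-associated collagen (12.70 against 3.52 in HCT116), and ALB (11.80 against 3.17 in RCM1). MDST8 followed with 60, led by SFRP1, a secreted WNT antagonist (12.27 against 3.48 in HUTU80), and HS3ST3A1, a heparan sulfate sulfotransferase (10.53 against 3.38 in OUMS23). OUMS23 had 56, led by the cancer-testis gene XAGE3 (11.80) and by MYL7, an atrial myosin light chain (11.39). HUTU80 had 50, led by the cancer-testis antigen MAGEA4 (11.23) and by KERA, a corneal proteoglycan (10.57). CAR1 had 41, led by KRT16, a stress keratin (11.03), and CXCL5, a neutrophil chemokine (10.47). COLO320HSR had 31, led by the transcription factor TFAP2B (10.47) and SV2C, a synaptic vesicle protein (9.31). The other 12 lines had 1 to 13 each, with the fewest in SW948.

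Among these lines, HCT116 was set apart by the cancer-testis antigen MAGEB2 (11.41) and by GTSF1, a germ cell factor (11.36). KM12 was set apart by THBS2, a matrix glycoprotein (11.55), and CLDN10 (8.19), and HT55 by GZMB, the cytotoxic protease granzyme B (10.49), and FZD10, a WNT receptor (9.76). RKO was set apart by MAP1LC3C (10.14) and BCL2A1, an anti-apoptotic protein (11.29), and SW48 by GPR15 (10.80) and GNAT3, a G protein of taste cells (11.11). CL40 was led by PPBP, a platelet chemokine (9.91), and the interferon-induced IFI44L (7.80), and LS180 by PIGR, the carrier of secretory antibodies (9.26), and PTGDR (8.01). SW1463 was led by MTTP, which loads lipid onto lipoproteins (9.12), and ERICH4 (7.99), and SNUC1 by MRLN (8.70) and CPXCR1 (8.19). RCM1 was led by CST7 (8.52) and C11orf21 (7.96), LS513 by PEX5L (6.72) and RPTN (6.68), and SW948 by LCN15 (8.16). MAGE, XAGE, keratin and CXCL genes have relatives of similar sequence, and their identity is less certain than that of single-copy genes.

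Genes at least 3 log2 units below every other line were fewer, 94 in all, with 19 in OUMS23, 16 in HUTU80 and 11 in COLO320HSR. ANXA2, a membrane-binding annexin, was 3.27 in COLO320HSR and at least 12.02 in every other line, although its pseudogenes are close in sequence. GSTP1, a glutathione transferase, was 3.88 in KM12 against a next lowest value of 10.05. MET, the hepatocyte growth factor receptor, was 3.84 in HUTU80 against 9.01, and JUN, a subunit of AP-1, was 3.24 in HT55 against 8.24. AP3S1, an adaptor subunit of vesicle transport, was 3.74 in SNUC1 against 9.51, and EID1 was 3.20 in SW48 against 8.65. NF2, which encodes the tumour suppressor merlin, was 3.74 in CAR1 against 6.75, and PDLIM1 was 3.29 in RKO against 7.31. HK1, a hexokinase, was 4.24 in LS513 against 7.28, PLS3, an actin bundler, was 2.78 in SW948 against 6.97, and ECH1, an enzyme of fatty acid oxidation, was 4.91 in RCM1 against 8.67. EMC4 was 5.05 in CL40, IGF2BP2 3.19 in NCIH716, TCEAL1 2.56 in HCT116, SMIM30 2.99 in LS180, SMIM20 3.53 in MDST8 and IMPACT 3.31 in SW1463. The histone gene H4C3, one of a family of near-identical copies, was 5.97 in OUMS23 against 11.78. A gap does not require the gene to be undetected in the low line. These counts are set by a fixed gap, not by a test: gaps of 2 or 4 log2 units gave 819 or 207 high and 211 or 46 low genes, and the mean of all probe sets gave 51 low genes, 49 of them among the 94.

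**Figure D3:**
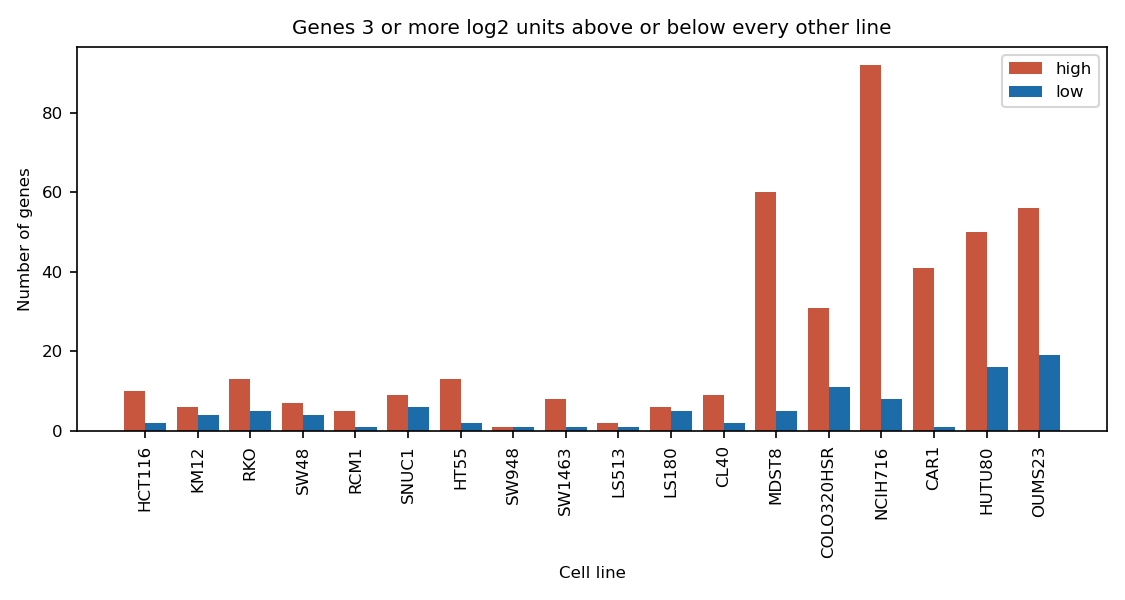
Number of genes (y axis) at least 3 log2 units above (red) or below (blue) every other line, for each of the 18 cell lines (x axis). NCIH716 has 92 high genes and SW948 has 1, and OUMS23 has 19 low genes.

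The fourth comparison asked whether genes known to act together rose and fell together across the lines. CDH1 and its repressor ZEB1 formed separate clusters. In RKO, MDST8, COLO320HSR, NCIH716 and HUTU80, CDH1 was at background (3.16 to 4.08) and ZEB1 was 8.53 to 10.66. In the other 13 lines CDH1 was 8.81 to 11.58 and ZEB1 was at background (2.82 to 4.68). ESRP1, an epithelial splicing factor, divided the lines as CDH1 did (3.31 to 3.55 in the 5 lines, 6.88 to 10.95 in the 13). EPCAM was at background in MDST8, COLO320HSR and HUTU80 (3.74 to 4.09) but 7.55 to 9.19 in RKO and NCIH716, and VIM was 8.30 in RKO and 12.31 to 13.19 in the other 4 of these lines. Because of such clusters no pooled correlation is given for 10 of the 20 pairs that could be measured. Of 14 tests within clusters of at least 6 lines, 1 passed: EPCAM and ZEB1 in the 13 lines (r = −0.72, permutation p = 0.00233, adjusted p = 0.0326; rho = −0.40, permutation p = 0.176). Without HCT116 and OUMS23 it was r = −0.35, so it rested on those lines, and ZEB1 was at background in all 13. CDX1, CDH17, AGR2 and TFF3 were also clustered, so CDX2 with CDX1 or CDH17, SPDEF with AGR2 and MUC2 with TFF3 were tested within clusters only, and none passed. With the mean of all probe sets AGR2 formed no clusters, and SPDEF with AGR2 passed (r = 0.54, adjusted p = 5.5e-04). CDX2, a homeobox regulator of intestinal identity, was highest in COLO320HSR (11.44), where CDX1 was 4.23. SPDEF, a goblet cell regulator, was highest in NCIH716 (7.85) and MUC2, the main intestinal mucin, in CL40 (7.79).

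**Figure D4:**
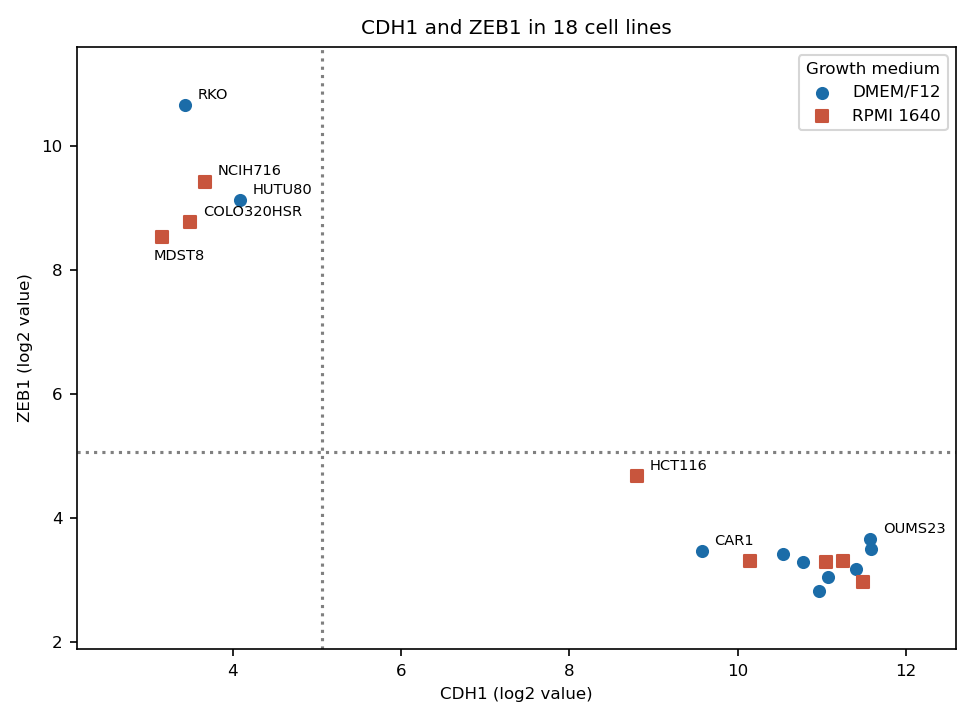
CDH1 (x axis) against ZEB1 (y axis), log2 values of the 18 cell lines, with circles for DMEM/F-12, squares for RPMI-1640 and dotted lines at the background level of 5.06. In 5 lines CDH1 lies between 3.16 and 4.08 with ZEB1 at 8.53 or more, and in 13 lines CDH1 lies at 8.81 or more with ZEB1 at 4.68 or less.

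Among the 10 pairs without clusters, 6 were correlated at adjusted p under 0.05. TAP1 and PSMB9, which supply peptides to MHC class I, had r = 0.81 (permutation p = 4e-05, adjusted p = 4e-04; rho = 0.80, p = 9e-05), with r = 0.87 in the 10 DMEM/F-12 lines and 0.82 in the 8 RPMI-1640 lines. CAV1 and CAV2, the coat proteins of caveolae, had r = 0.80 (permutation p = 1.7e-04, adjusted p = 8.5e-04; rho = 0.81, p = 1e-04), with 0.74 and 0.85 within the media. Both held without the 2 lines farthest from the median (r = 0.78 and 0.73). In the WNT set, ASCL2 with LGR5, a receptor of crypt stem cells, had r = 0.65 (permutation p = 0.00496, adjusted p = 0.0124; rho = 0.67, p = 0.0033; 0.79 and 0.50 within the media; 0.62 without HCT116 and HUTU80). AXIN2 with NKD1, another feedback inhibitor, had r = 0.61 (permutation p = 0.00678, adjusted p = 0.0136; rho = 0.66, p = 0.00384; 0.54 and 0.75 within the media; 0.51 without RKO and NCIH716). AXIN2 with ASCL2 had r = 0.58 (permutation p = 0.0137, adjusted p = 0.0228; rho = 0.39, p = 0.113; 0.42 and 0.78 within the media). Without RKO and NCIH716 it was weaker but still positive (r = 0.45, permutation p = 0.0759). INSM1, a neuroendocrine transcription factor, and CHGA, a granin, had r = 0.98 (permutation p = 0.00257, adjusted p = 0.00857) but rho = 0.37 (p = 0.133). That correlation rested on NCIH716, where they were 9.43 and 9.74 and above background in no other line; without it and SW1463 r was −0.04, and within the media r was 0.52 and 1.00.

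The 4 pairs that did not pass were CCN1 with CCN2 (r = 0.45, adjusted p = 0.0868), CDKN1A with MDM2 (r = 0.40, adjusted p = 0.122), MYC with NCL (r = 0.38, adjusted p = 0.122) and AXIN2 with LGR5 (r = 0.38, adjusted p = 0.122). CDKN1A, a cell cycle inhibitor, was at background in NCIH716 (4.13) and COLO320HSR (4.24), and MDM2, the ligase for p53, was highest in OUMS23 (9.68). LGR5 was highest in LS180 (9.90), and NCL, the nucleolar protein nucleolin, had an SD of 0.26. Some calls turned on 1 line. Without KM12 AXIN2 with LGR5 passed (r = 0.58, adjusted p = 0.0206). Without SNUC1 or OUMS23 both CDKN1A with MDM2 (r = 0.51 and 0.53, adjusted p = 0.0467 and 0.0366) and CCN1 with CCN2 (r = 0.55 and 0.61, adjusted p = 0.0344 and 0.0162) passed. INSM1 with CHGA failed without NCIH716 (r = 0.46, adjusted p = 0.0945); without SW1463 its r was 0.99 and the adjusted p 0.0558, so the p alone moved. AXIN2 with ASCL2 failed without NCIH716 (r = 0.52, adjusted p = 0.0656) and with the mean of all probe sets (r = 0.46, adjusted p = 0.0791). Without HCT116 or MDST8 the AXIN2 values, and without SW48 the ASCL2 values, formed clusters, so AXIN2 with ASCL2, AXIN2 with NKD1 (HCT116, MDST8) and ASCL2 with LGR5 (SW48) had no pooled value there.

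The last comparison asked whether the 10 lines grown in DMEM/F-12 differed from the 8 grown in RPMI-1640. No gene of 12766 passed at adjusted p under 0.05 in limma (smallest adjusted p = 0.950), and 319 had an unadjusted p under 0.05, of which 130 were higher in DMEM/F-12; chance alone would give 638.3. The other fits, with array weights, without the trend, with robust moderation, with other probe set rules, floors or scaling, and without each line, also gave 0 genes, with 172 to 644 at unadjusted p. The genes with the smallest p are given as values. ECHDC2 averaged 8.15 ± 0.44 (SD, n = 10) in DMEM/F-12 and 6.33 ± 1.06 (SD, n = 8) in RPMI-1640. TESK2, a kinase, averaged 5.43 ± 0.67 and 4.41 ± 0.41, and NINJ2-AS1, a non-coding transcript, 4.89 ± 1.10 and 3.42 ± 0.51. PLA2G4A, which releases arachidonic acid from membranes, averaged 4.66 ± 2.16 in DMEM/F-12 and was 3.33 log2 units higher in RPMI-1640 (SE 0.88). PELI2, a ubiquitin ligase, averaged 3.94 ± 0.34 and 6.24 ± 1.95, and METTL23 9.60 ± 0.37 and 10.15 ± 0.16. Each line was grown in 1 medium, so medium and line identity cannot be told apart.

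At the level of lists, camera with its preset correlation of 0.01 placed epithelial genes higher in DMEM/F-12 (median difference 0.84 log2 units over 23 members, adjusted p = 9.67e-04). It placed neuroendocrine genes (−0.76, 13 members, adjusted p = 0.00104) and cholesterol and fatty acid synthesis genes (−0.36, 17 members, adjusted p = 2.19e-05) lower. With an estimated correlation none of the 3 held (adjusted p = 0.879 for each), and fry called no list (adjusted p = 0.869 for each). Adjusted over the list alone, 1 gene passed, CPE of the neuroendocrine list (difference −3.08 log2 units, unadjusted p = 0.00178), and over all genes none did. CPE was above background in 5 lines, highest in NCIH716 (11.35), COLO320HSR (8.30) and HCT116 (8.19).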

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

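All alternatives were planned before the data were examined. With a background level at the 99th percentile (8.61 log2 units) 2516 variable genes, 188 high and 26 low restricted genes were left, as fewer genes and lines count as detected. That level may reflect signal of KERA and RLBP1, which belong to the background set. A range of 2 or 4 log2 units gave 8105 or 3254 variable genes, and gaps of 2 or 4 gave 819 or 207 high and 211 or 46 low restricted genes, by construction. The mean of all probe sets gave 51 low restricted genes; the cause was not tested. Random lists matched on mean and SD left 134 list positions called, 132 of them among the 216; the cause was not tested. With an estimated correlation camera called 0 lists between the media. Leaving out 1 line at a time gave 4604 to 4860 variable genes, a median similarity of 0.51 to 0.55, 18 to 20 coherent lists, 369 to 441 high and 90 to 103 low restricted genes, 4 to 8 correlated pairs and 0 to 0 genes between the media. The mean r of the neuroendocrine list ran from −0.034 (without replicate 15, NCIH716) to 0.50. Over all alternatives, those without 1 line included, list coherence stayed on its side of the threshold in 525, newly passed in 11, failed in 11 and turned negative in 1, and pair correlations stayed in 201, newly passed in 5 and failed in 6; in 8 more, without HCT116, SW48 or MDST8, clusters left no pooled value, 6 of them for correlated pairs. With the mean of all probe sets, the probe set with the largest SD and array scaling, of 171 named genes 133, 165 and 171 had a range within 1 SD, 154, 164 and 151 the same highest line and 130, 159 and 162 the same lowest line. Signal over background limits the reading of genes near 5.06.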

Other observations

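The tests of neighbouring gene runs against shuffled gene order, of leukocyte RNA and of the medium for the interferon genes, of all other probe sets of the NCIH716 run, and of the count of genes at adjusted p over other splits were chosen only after the results were seen, as were the genes named here. Of 36 combinations of line and side 16 held a run past the adjusted threshold, and over all lines 18 low and 16 high runs lay beyond 95% of shuffles in their line. Gene families that lie side by side in the genome stood low or high together, each of those below in more than 1 line. In COLO320HSR the S100 calcium-binding genes S100A10 (3.41), S100A11 (3.94), S100A6 (2.88), S100A4 (4.21), S100A2 (3.36), S100A16 (4.35) and S100A14 (3.37) were at background while their neighbour S100A13 was 9.51 (permutation p adjusted over these combinations, 0.00719), and HUTU80 had a low block there as well (adjusted p = 0.0150). CL40 stood high for the neutrophil chemokines CXCL8 (11.54), CXCL1 (10.66), CXCL3 (10.29) and CXCL2 (12.11; adjusted p = 0.00719), and this run was also high in LS180 (adjusted p = 0.00719), KM12 (adjusted p = 0.0150) and SNUC1. RKO stood high for the metal-binding metallothioneins MT2A (12.83), MT1E (12.84), MT1F (11.97) and MT1X (12.40; adjusted p = 0.0120), and these were also high in LS180 and, short of the threshold (adjusted p = 0.0683), in MDST8. They were low in KM12, RCM1 and SNUC1, where MT2A was 6.76, 7.83 and 4.46. NCIH716 was low for the antiviral membrane proteins IFITM1 (3.59), IFITM2 (4.67) and IFITM3 (5.36; adjusted p = 0.0221), and KM12 had them at 3.89, 5.10 and 5.53 (adjusted p = 0.0135). The homeobox gene HOXB9, which patterns the hindgut, was 3.40 in KM12, 4.22 in LS180 and 3.29 in OUMS23, and 6.03 or more in the other lines. Members of the S100, CXCL, metallothionein and IFITM families have relatives in sequence, so probe sets shared between relatives are not ruled out for them. Among the other runs, which also hold genes near the panel median, OUMS23 had 3 low ones with lowest windows of −6.02 (adjusted p = 0.0150), −5.97 and −5.41, and SNUC1 had another with −3.42.

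SNUC1 was low for a run of neighbouring genes. Of 10 genes from TRIM36 to DMXL1, 7 were lowest there: PGGT1B (3.58; median of the other lines 8.15), CCDC112 (2.40; 5.29), FEM1C (3.73; 7.44), TMED7 (3.23; 8.62), ATG12 (3.29; 8.93), AP3S1 (3.74; 10.74) and COMMD10 (2.99; 8.84). Scattered probe failure on 1 array is argued against by gene order: no shuffle reached the window of −5.63 (most extreme −4.56, p = 0.000999, the smallest that 1000 shuffles can give). A sequence variant under single probe sets is argued against by the other probe sets of these genes, of which 6 of 6 (100%) with a panel median above background were lowest in SNUC1 (8 of 11 with no such filter). DTWD2 (5.23; 5.51) and DMXL1 (6.27; 6.54), at the end of the run, were near the other lines, and TRIM36 (3.67; 5.61) was not lowest in SNUC1. Just before the run SRP19 was 8.62 against 10.31, REEP5 9.16 against 10.22 and DCP2 6.66 against 8.68, so lower values reached beyond it on that side. Just after it TNFAIP8 was 6.64 against 7.94, while HSD17B4 (10.14 against 9.64) and SRFBP1 (7.44 against 6.86) were higher. None of these was lowest in SNUC1. A loss of the part from PGGT1B to COMMD10 in SNUC1 could give the values of that part. It stays an open hypothesis, since DNA was not measured and no biological explanation was tested.

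NCIH716 had a run of high neighbouring genes next to MYC. Of 10 genes from TATDN1 to MYC, 8 were highest there, among them MTSS1, an actin regulator (12.53; median of the other lines 5.85), NSMCE2 (12.60; 8.29), WASHC5 (12.31; 8.26) and SQLE (12.98; 10.22), while MYC was 11.68 against 11.58 and PVT1, beyond it, 5.34 against 7.18. No shuffled order reached the window of 4.05 (most extreme 3.42, p = 0.000999), so the high values lay side by side in the genome. Failed probes would lower a value, so this does not weigh on probe failure as a source of high values. All 8 other probe sets above background in NCIH716 (100%) were highest there, which decides nothing because the filter reads that line. Of all other probe sets with no filter 11 of 12 (91.7%) were, so the high values did not rest on the chosen probe sets alone. A variant under a probe set would likewise lower a value, so these counts do not weigh on it. TATDN1, at the other end from MYC, was 9.26 against 10.06. A gain of the part from NDUFB9 to POU5F1B could give this pattern and stays open, as DNA was not measured and no biological explanation was tested.

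CL40 stood high for all 22 interferon response genes, which respond to antiviral signalling. RNA from leukocytes is argued against by the leukocyte genes, whose median deviation in CL40 was 0.0081 log2 units (SD over members 0.25); none of the 11 was above background there, and PTPRC was 3.43. An effect of the medium shared by all lines grown in it is argued against, since CL40 lay 2.72 log2 units above the next highest of them, which was at 0.41. A response of CL40 alone to its medium is not addressed and stays open. CL40 was picked for its high median, and no line was grown in both media. Signalling within the line may raise these genes and stays open, since no biological explanation was tested.

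For the growth medium, chance cannot be excluded: 85 of 100 splits of the lines into 10 and 8, the real one included, gave at least the real 319 genes at unadjusted p, with 2065 as the highest other. At adjusted p the real count was 0, which all 100 splits must reach, so that count decides nothing; the highest other was 33. The split with 33 genes put HCT116, KM12, SW48, MDST8, NCIH716, CAR1, HUTU80 and OUMS23 together. It was picked as the largest of the drawn splits, so its count alone cannot show a structure of the samples, and no structure was tested.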
